A study of Streptomyces coelicolor A3(2) with 3 samples.

How the data were processed

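Gene expression was measured in 3 RNA samples of Streptomyces coelicolor A3(2), 1 per group: colonies at the microgravity position in flight, at the simulated 1g position in flight, and at static 1g on the ground. Groups were taken from the labels. Per the labels' protocols, RNA was extracted with liquid nitrogen and Trizol and purified on columns, 2 µg were reverse-transcribed and transcribed to cRNA, and 1.65 µg of cRNA was labelled with Cy3. With 1 array per group no test across groups exists, so every comparison describes 2 arrays, and the number of arrays limits the precision.

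Each array came as scanner output on a linear intensity scale, made with Agilent Feature Extraction 10.7.3.1, per the file headers. The processed signal in it is the spot intensity after background subtraction and spatial detrending, per the file headers, and is not normalized between arrays. The authors also deposited a value table in log2 units with 1 value per probe; how it was made is not given in the sources used here. Its 3 columns have nearly the same quantiles and a median of 7.72, and they correlate with the log2 processed signal of their own array at r = 0.9999, so its scale and direction are settled and its exact normalization steps are not. The authors' 2-fold tables hold those log2 values and a linear fold (ratio of microgravity over the control), filtered by the authors at 2-fold, with locus tag, product and position. A single probe past 2-fold in the value table is missing from the table against ground.

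Spots marked as outliers by the scanner software were left out (197, 196 and 176 of 14916 non-control spots), and the log2 processed signals of the remaining spots of a probe were averaged. Of 8116 probes, 680 have 11 spots and 7436 have 1. The 75th percentile over probes of each array was subtracted, after which the medians were -1.39, -1.41 and -1.44. A probe was compared where it was well above background and not saturated on both arrays; probes with every spot left out have no value. A probe was called by the fixed size of 2-fold. A probe not well above background on 1 array of a pair has only a bound, taken as the brighter value minus the higher of the dim value and the lowest value among probes well above background on that array: 4, 27 and 27 probes were in this state in the 3 comparisons, of which 0, 2 and 3 had a bound of at least 2-fold. Where the dim value is the higher, the bound is the measured difference and no strict lower limit.

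The scanner files and the value table name probes only by design number. The authors' tables pair 717 probes with as many locus tags, 702 on the chromosome, 14 on plasmid SCP1 and 1 on plasmid SCP2, and 702 of the tags were matched in the RefSeq gene table of assembly ASM20383v1, used for gene names and neighbour order. This changed 2 planned steps. The median and percentile of each whole gene list could not be had, so list members in the authors' tables were counted, with the share of 10000 random lists of the same number of loci that held as many, and for contiguous clusters the number of same-length blocks of neighbouring loci. Random lists draw loci independently and neighbours change together, so each list was also moved along the chromosome by every offset with its spacing kept (7619 shifted lists, its own place included), a test chosen after seeing the data; medians cover the named members only, which entered by passing 2-fold against some control, and are given for lists with at least 3 of them. Windows of 11 neighbouring loci were ranked by their number of called loci, not by a median, against 100 shuffled gene orders, and up to 5 non-overlapping windows per direction past the highest shuffled count were kept; the text gives a part of them, chosen after their values were seen.

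The 27 gene lists, the comparisons, the rule for named genes and all but 3 alternatives were chosen before the data were examined. Named genes are, per comparison, the 8 largest and 8 lowest differences, up to 4 members per list with the largest absolute difference, 13 regulators where measured, and the 4 largest bounds among dim genes (only 2 dim genes have a name). Further list members and window members are given as part of their group. For the correlation of the comparisons that share the microgravity array, unchanged arrays were simulated 100 times with independent spot noise of 0.061 (SD, log2). Scatter between the 2 arrays of a pair was gauged on 10 spike-in probes, whose differences had standard deviations of 0.095, 0.18 and 0.090 in the 3 comparisons. This scatter leaves out a shift common to all probes and holds no variation between cultures, so it is a yardstick for the processing alternatives only.

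The calling steps were tested on simulated data with the 8116 real probes and the real spot noise, in which 200 probes were changed: all 50 probes raised 3-fold and all 50 lowered as much were called, none of 50 raised 1.5-fold, and 0 of 7916 unchanged probes. This checks the steps only: the simulation holds no variation between arrays or cultures, so it gives no rate of false calls for the comparisons. Alternatives were normexp background correction with an offset of 50, quantile normalization, median scaling, cyclic loess, spike-in scaling, the authors' value table, other background filters, a 3-fold limit, and windows of 7 loci. R 4.3.3 with limma 3.58.1 read and scaled the arrays, and Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 did the rest.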

Results

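Colonies of wild-type Streptomyces coelicolor A3(2), a filamentous soil bacterium that makes several antibiotics, were grown from spores on JCM42 agar for 16.5 days at 23 °C during the Shenzhou-8 mission and on the ground. A culture flew at a microgravity position of the BIOBOX incubator, another flew at a position with simulated 1g, and the last stood at static 1g on the ground. Total RNA from each was labelled with Cy3 and hybridised to 1 one-colour Agilent array, so that each of the 3 groups holds 1 array and no difference below has a replicate check or a p-value. All 3 arrays lay on 1 slide and came from 1 scan. Each array carried 8116 non-control probes, of which 6, 6 and 33 were not well above background on the microgravity, simulated 1g and ground arrays, and none was saturated. The median processed signals were 239, 233 and 168 intensity units, respectively. Repeat spots of the same probe differed by a median standard deviation of 0.059, 0.057 and 0.067 on the log2 scale, which is technical error within an array only. Locus tags were paired with 717 of the probes, those in the authors' deposited 2-fold tables, and the other 7399 probes are unnamed here. Differences are given as log2 of the first array over the second after scaling to the 75th percentile, and "higher" and "lower" describe these arrays.

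The comparison of microgravity with simulated 1g, both in flight, addressed gravity within the incubator. Genes of nitrogen assimilation had the highest list median on the microgravity array. Glutamine synthetase I (SCO2198) was 4.96-fold higher, glutamine synthetase II (SCO2210) was 4.80-fold higher and the PII nitrogen regulatory protein (SCO5584) was 4.59-fold higher than in simulated 1g. Genes of the thiol stress response were also higher, among them the sigma factor gene sigR (SCO5216) at 2.82-fold. The chaperonin genes groES (SCO4761) and groEL (SCO4762) were 2.54-fold and 2.37-fold lower in microgravity.

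Of 8106 probes compared, 184 were at least 2-fold higher and 84 at least 2-fold lower in microgravity than in simulated 1g. The 8 largest differences belonged to NAD(+) synthase (SCO2238), with a log2 difference of 3.13, a dehydrogenase (SCO2651) with 2.93, carbonic anhydrase (SCO6055) with 2.83, a uroporphyrinogen-III synthase and response regulator fusion (SCO2958) with 2.78, the small nitrite reductase subunit (SCO2488) with 2.66, an ABC transporter ATPase (SCO2746) with 2.62, the assimilatory nitrate reductase (SCO2473) with 2.52 and the LacI-family regulator next to that transporter (SCO2745) with 2.48. The 8 lowest belonged to SCO5109, a protein of unknown function, with -2.43, a fatty acid CoA ligase (SCO1330) with -2.22, a dicarboxylate symporter (SCO5436) with -2.20, SCO2527 with -2.15, SCO1329 with -1.82, a cation-transporting ATPase (SCO0860) with -1.81, the nitrate reductase subunit narG2 (SCO0216) with -1.69 and a membrane protein (SCO7613) with -1.68. The dicarboxylate symporter SCO5436 was higher in microgravity than on the ground, by 1.18, and its signal in simulated 1g was the highest of the 3 arrays.

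Among the fixed gene lists, 7 of the 13 nitrogen assimilation loci were in the authors' deposited table as higher, and 0 of 10000 random lists of 13 loci held as many, nor did any of 7619 shifts of the list along the chromosome other than its own place. The 10 named loci of this list had a median difference of 2.15, and the urease genes, such as SCO1234 with 0.82, were the lowest of them. Of 15 oxidative and thiol stress loci, 5 were in that table as higher: sigR, its anti-sigma factor gene rsrA (SCO5217) with 1.23, the thioredoxin reductase gene (SCO3890) with 1.25 and the thioredoxin genes SCO3889 with 1.05 and SCO0885 with 1.26; 3 of 7619 shifted lists held as many. Against the ground array the same 5 genes lay between -0.02 and 0.74, with a median of 0.26. The ectoine genes, which make a compatible solute, supplied the 4 higher members of the SigB and osmotic stress list, with 2.22 for ectoine synthase (SCO1866), 2.01 for SCO1865, 1.76 for SCO1864 and 1.05 for the hydroxylase SCO1867, and 26 of 7619 shifted lists held as many higher loci. In the same list the sigma factor genes SCO7278 and SCO6520 had differences of -0.99 and -0.30. Of the 8 heat shock loci, 3 were in the authors' table as lower (groES, groEL and the second groEL, SCO4296, with -0.86), which 17 of 7619 shifted lists reached, while clpB (SCO3661) had 0.51. The gas vesicle cluster had 4 of 10 loci higher, and 38 of 7610 blocks of 10 neighbouring loci held as many. In the coelibactin and zinc list 1 of 13 loci was higher, a metal-binding lipoprotein (SCO2505) with 1.13, as in 24.9% of random lists. Calls in the antibiotic clusters were few and mixed: redX (SCO5878) had 1.12 and the thioesterase SCO5894 -1.16 in the undecylprodigiosin cluster, and SCO5084 -1.002 in the actinorhodin cluster, and 39.0%, 22.6% and 22.6% of random lists held as many. Plasmid SCP1 had 3 higher and 1 lower of 324 loci, as many as in 97.7% and 97.9% of random lists.

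The comparison of microgravity in flight with static 1g on the ground joined flight and gravity. Of the 8 largest differences, 6 lay in 1 region near the left end of the chromosome, and gas vesicle and nitrogen assimilation genes were higher in microgravity as well. SCO0210, of unknown function, was 38.5-fold higher, the DNA-binding protein SCO0174 was 34.9-fold higher and the LuxR-family response regulator SCO0204 was 9.83-fold higher than on the ground. Genes of the calcium-dependent antibiotic, a lipopeptide, were lower, with the transporter gene SCO3224 at 4.04-fold, as were genes of the F0F1 ATP synthase, with subunit c (SCO5368) at 2.61-fold. The sporulation gene ssgB (SCO1541) was 3.73-fold lower.

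Of 8081 probes compared, 322 were at least 2-fold higher and 273 at least 2-fold lower in microgravity than on the ground. The 8 largest differences were those of SCO0210 with 5.27, SCO0174 with 5.12, SCO0167 with 4.64, the molybdate-type substrate-binding protein modA (SCO3704) with 4.56, SCO0173 with 4.55, SCO0181 with 4.50, the nitrite reductase small subunit SCO2488 with 4.21 and SCO0201 with 4.16. The 8 lowest were those of a magnesium chelatase (SCO5277) with -2.74, a sigma factor (SCO0194) with -2.69, a metallopeptidase (SCO6736) with -2.51, SCO3465 with -2.40, SCO3462 with -2.28, a secreted protein (SCO1105) with -2.28, an ABC transporter ATPase (SCO2257) with -2.27 and SCO3624 with -2.24. The chitinase SCO6345 was not well above background on the ground and measured 2.37-fold higher in microgravity. SCO6939, dim in the same way, measured 2.33-fold higher. In simulated 1g the same 2 genes measured 2.03-fold and 1.27-fold higher than on the ground. For both genes the bound equals the measured difference, so it rests on a dim ground signal and is no strict lower limit.

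**Figure D1:**
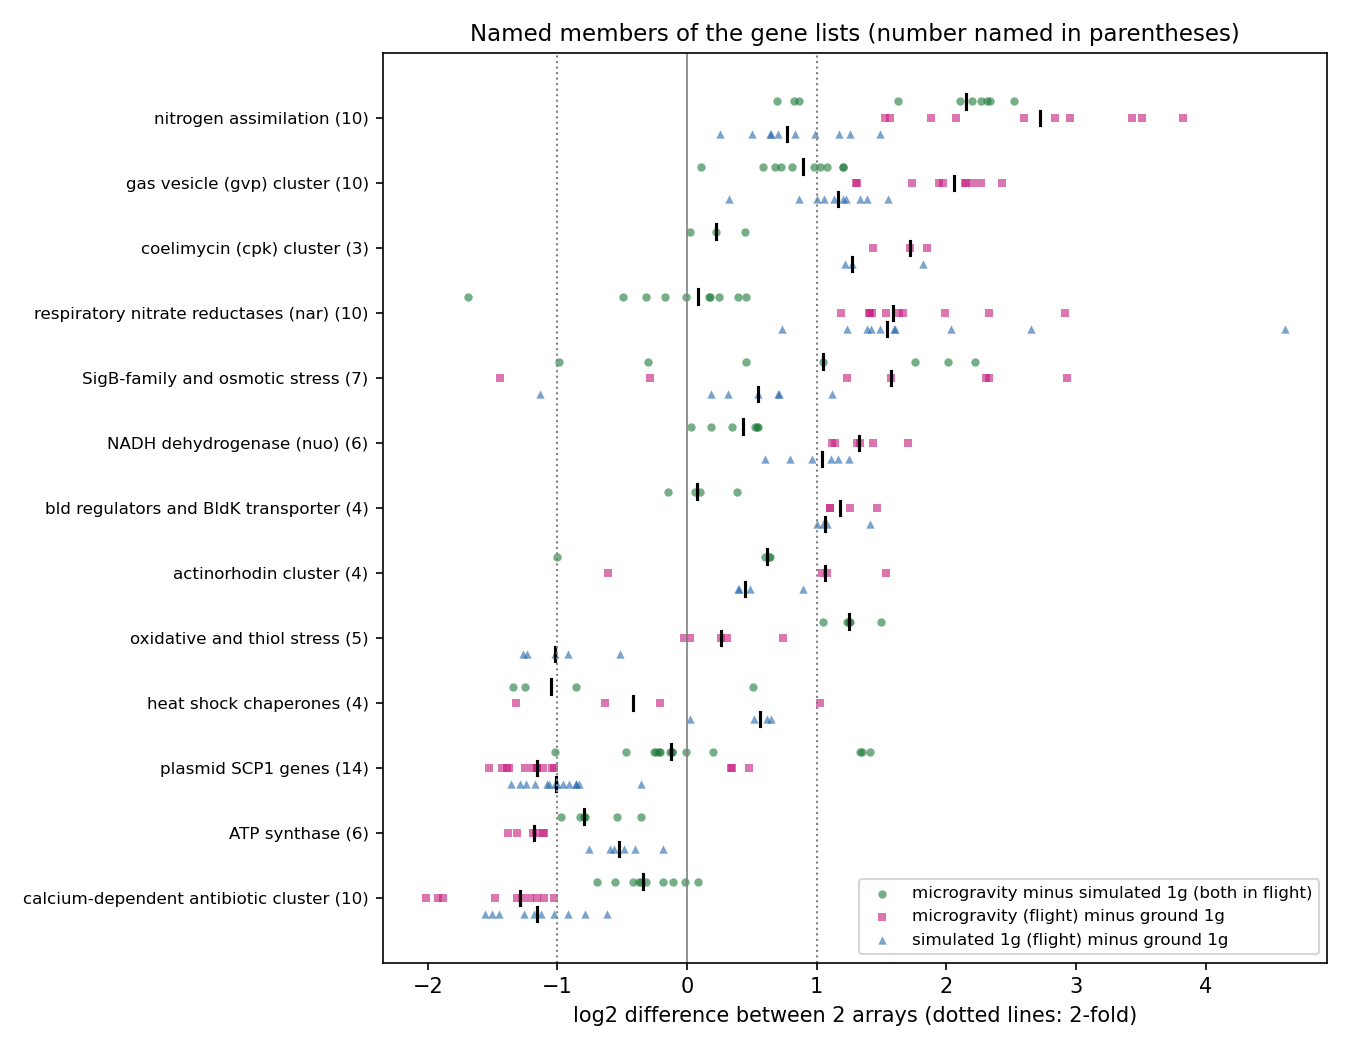
Log2 differences (x axis) of the named members of the 13 gene lists with at least 3 named members, as circles for microgravity minus simulated 1g, squares for microgravity minus ground and triangles for simulated 1g minus ground, with a black bar at each median. Nitrogen assimilation has medians of 2.15, 2.72 and 0.77 in this order, and the calcium-dependent antibiotic cluster -0.34, -1.29 and -1.15; members enter by being in a 2-fold table against either control.

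In the authors' deposited table for this comparison, 10 of 13 nitrogen loci, 10 of 10 gas vesicle loci and 10 of 12 respiratory nitrate reductase loci were higher, and 0 of 10000 random lists of the same sizes held as many in each case. Of 7619 shifted lists, 1 (nitrogen, its own place) and 4 (nitrate reductases) held as many. For the gas vesicle genes, which lie side by side, 9 of 7610 blocks of 10 neighbouring loci held as many. Among nitrogen genes the large nitrite reductase subunit (SCO2487) had 3.83, the nitrate reductase SCO2473 had 3.51 and glutamine synthetase II (SCO2210) had 3.43. The gas vesicle members ranged from 1.30 to 2.43, the highest being SCO6505. The nitrate reductase members, which let nitrate serve as an electron acceptor, included narG2 (SCO0216) with 2.92 and narH2 (SCO0217) with 2.33. These genes, with SCO0218 and SCO0219, lie in the region near the left end of the chromosome, so their calls are not separate from it. Of the 14 loci of NADH dehydrogenase, 6 were higher, the most being subunit L (SCO4573) with 1.70, and 73 of 7606 blocks of 14 neighbouring loci held as many. Of 13 loci of the bld list 4 were higher, all of them in the BldK oligopeptide importer, with SCO5113 at 1.46 the highest, and 102 of 7619 shifted lists held as many. The phosphate regulators phoR (SCO4229) and phoP (SCO4230) had 1.15 and 1.01, and 7.04% of random lists held as many as these 2 of 11 phosphate loci. The ectoine genes and a Dps-type DNA-binding protein (SCO0596, 1.57) made 5 higher members of the osmotic stress list, as many as in 34 of 7619 shifted lists, while the sigma factor SCO6520 of that list had -1.44. The heat shock list held 1 higher locus, clpB (SCO3661) with 1.02, and 1 lower, groES (SCO4761) with -1.32, which 2837 and 2135 of 10000 random lists reached. Spike-in scaling ended the groES call.

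In the same comparison, 10 of the 40 loci of the calcium-dependent antibiotic cluster were lower and none higher, and 0 of 10000 random lists held as many. Because neighbouring loci move together, blocks of 40 neighbouring loci were counted too: 42 of 7580 such blocks, overlapping ones included, held at least 10 lower loci. Spike-in scaling left 4 of the 10 past 2-fold. The members ranged from -2.01 for SCO3224 to -1.03 for the dioxygenase SCO3229, and included absA1 (SCO3225) with -1.48 and absA2 (SCO3226) with -1.22, a 2-component system that made up the 2 lower members of the list of 17 antibiotic regulators (9.08% of random lists held as many). Of these 2 regulators, 1 stayed past 2-fold under spike-in scaling. Of 8 ATP synthase loci 6 were lower, between -1.38 and -1.10, and 3 of 7612 blocks of 8 neighbouring loci held as many; under spike-in scaling 1 of the 6 stayed past 2-fold and the median was -0.80 in place of -1.18. Both named ram genes of the SapB cluster, ramB (SCO6684) with -1.13 and its activator ramR (SCO6685) with -1.46, were lower, and 182 of 7615 blocks of 5 neighbouring loci held as many; 1 of the 2 stayed past 2-fold under spike-in scaling. Single lower members were ssgB in the sporulation list and the ketosynthase SCO5318, with -1.01, in the whiE spore pigment cluster, which 42.8% and 21.1% of random lists reached, as did 1326 of 7612 blocks for the whiE cluster. Under spike-in scaling ssgB stayed past 2-fold and SCO5318 did not. In the other antibiotic clusters few loci were in the table as higher: 3 of 22 actinorhodin loci, of which SCO5075 had 1.53 while SCO5084 of that cluster had -0.61, 2 of 22 undecylprodigiosin loci (redX, SCO5878, with 1.08 and the thioesterase SCO5894 with 1.22) and 3 of 20 coelimycin loci, of which SCO6283 had 1.85. Of 10000 random lists, 5.74%, 22.5% and 4.80% held as many higher loci as these 3 clusters, as did 896 of 7598, 1584 of 7598 and 792 of 7600 blocks of neighbouring loci, so none of the 3 stands out as a cluster. The terpene list had 2 higher members, SCO0185 with 1.08 and SCO0188 with 1.76, as many as in 27.7% of random lists. Both lie in the region near the left end of the chromosome, so their calls are not separate from it. The ribosomal protein list had 1 higher member (rpsC, SCO4708, with 0.93 after 75th percentile scaling), as in 72.2% of random lists. On plasmid SCP1, 11 of 324 loci were lower, a number that 39.5% of random lists reached, with 3 left past 2-fold under spike-in scaling.

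No member of 5 lists was in either deposited table: chaplins and rodlins, which coat aerial hyphae and spores, cell division and chromosome partitioning, glycolysis and the TCA cycle, DNA repair and the SOS response, and siderophores. None of the 13 pathway and developmental regulators chosen beforehand, such as actII-ORF4 (SCO5085), redD (SCO5877), cdaR (SCO3217) and adpA (SCO2792), was in either table, and their values are not analysed here.

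The comparison of simulated 1g in flight with static 1g on the ground set the 2 controls against each other at the same nominal gravity. Most named genes between SCO0162 and SCO0220 were higher in flight here as well, with SCO0174 at 59.4-fold, SCO0167 at 36.5-fold and SCO0210 at 35.0-fold. The metallopeptidase SCO6736 was 9.75-fold lower and SCO3462 was 7.74-fold lower in flight. Of the thiol stress genes, sigR (SCO5216) was 2.35-fold and the thioredoxin reductase gene (SCO3890) 2.41-fold lower in simulated 1g than on the ground, calls that spike-in scaling ended.

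Of 8083 probes compared, 233 were at least 2-fold higher and 203 at least 2-fold lower in simulated 1g, and 133 of these have no name here, since the deposited tables cover only comparisons with microgravity. Among named genes the 8 largest differences were those of SCO0174 with 5.89, SCO0173 with 5.39, SCO0167 with 5.19, SCO0210 with 5.13, SCO0181 with 5.01, a lipoprotein (SCO7460) with 4.98, SCO0215 with 4.82 and SCO0169 with 4.74. Unnamed probes among those compared ranged from -1.81 to 1.69. They are in neither of the authors' tables of 2-fold differences from microgravity, which by itself limits how far they can differ here. The 8 lowest were those of SCO6736 with -3.28, SCO3462 with -2.95, a phosphorylase (SCO3463) with -2.62, a zinc metalloprotease (SCO5795) with -2.55, SCO3465 with -2.51, SCO1105 with -2.47, SCO4466 with -2.41 and a thioredoxin (SCO5438) with -2.32. Of the list members with a name, 9 of 10 nitrate reductase, 8 of 10 gas vesicle, 3 of 6 NADH dehydrogenase, 3 of 4 bld and 3 of 3 coelimycin genes were at least 2-fold higher, and 7 of 10 genes of the calcium-dependent antibiotic cluster at least 2-fold lower (3 under spike-in scaling). Spike-in scaling raised the NADH dehydrogenase count from 3 to 6. For 10 nitrogen genes the median was 0.77, with 3 of them at least 2-fold higher (8 under spike-in scaling, with a median of 1.19), and for 6 ATP synthase genes it was -0.53, with none past 2-fold. The thioesterase SCO5894 of the undecylprodigiosin cluster was higher by 2.38, while redX (SCO5878) had -0.04. These named genes entered the tables through a difference from microgravity, so their counts here are not a survey of each list.

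**Figure D2:**
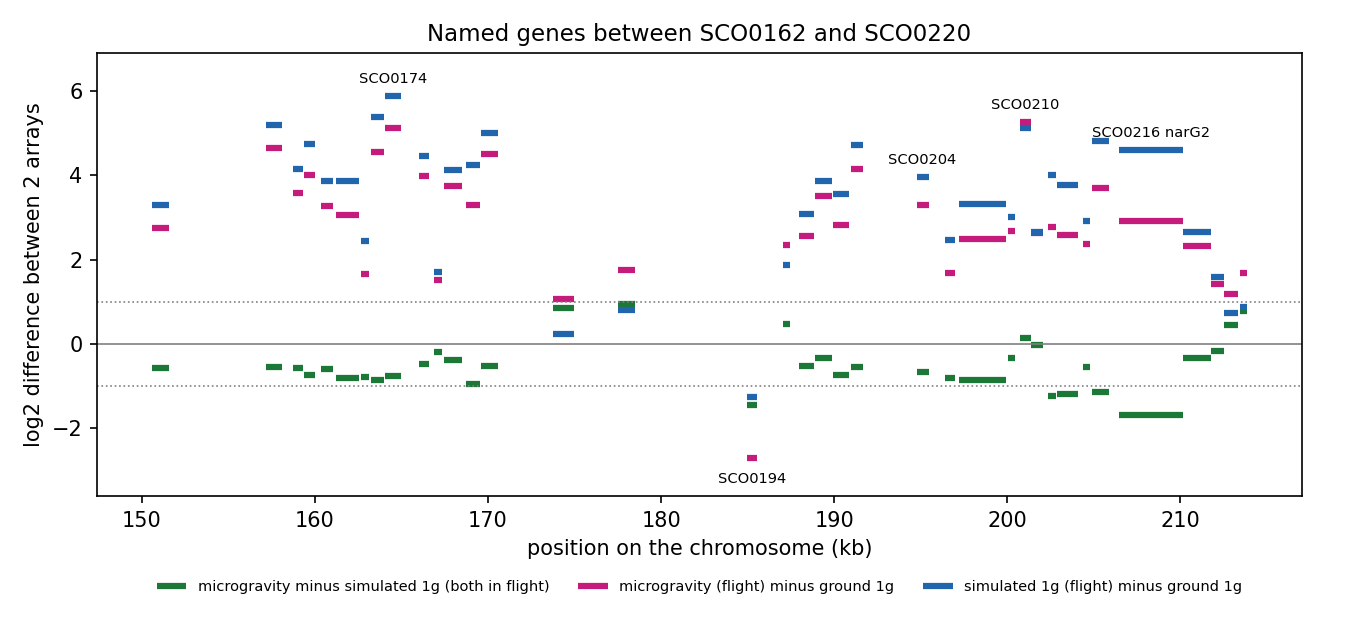
Named genes between SCO0162 and SCO0220 drawn at their chromosome positions (x axis, kb), each bar spanning the gene at its log2 difference (y axis) in the 3 comparisons given by colour. Both flight arrays lie above the ground array for nearly all of these named genes, up to 5.89 at SCO0174. SCO0194 lies below the ground array, at -2.69 in microgravity and -1.24 in simulated 1g. Genes have a name only by passing 2-fold between microgravity and a control, and loci without a name are not drawn.

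Windows of 11 neighbouring loci located these runs. Only named loci could be called, so each count is a lower limit. In simulated 1g against ground, 133 called probes have no name, and windows can lie only where differences from microgravity gave names. Shuffled gene orders break up neighbours that change together, so passing them says little about any single run. Between SCO0207 and SCO0217 (chromosome, 196386 to 211751) all 11 loci were at least 2-fold higher in both flight arrays than on the ground, with median differences of 2.63 in microgravity and 3.33 in simulated 1g, while the highest of 100 shuffled gene orders reached 5 and 4. Between SCO0167 and SCO0179 (157189 to 168514) 10 of 11 were higher, with medians of 3.87 and 4.30, and between SCO0194 and SCO0204 (184958 to 195461) 6 of 11. The gas vesicle genes and their neighbours from SCO6497 to SCO6507 (7190961 to 7198890) were all higher in microgravity than on the ground, with a median of 1.97. Against simulated 1g, 8 of 11 loci from SCO2480 to SCO2490 (2670982 to 2681772), which hold the nitrite reductase genes, were higher with a median of 2.01, and SCO0859 to SCO0863 were lower with a median of -1.59. Lower runs against the ground held arginine biosynthesis genes from SCO1569 to SCO1579 (1679335 to 1690436), 7 of 11 with a median of -1.63 in microgravity, and SCO3455 to SCO3465 (3814870 to 3825016), 7 of 11 with -1.46 in microgravity and 9 of 11 with -2.07 in simulated 1g. Next to it, 8 of 11 loci from SCO3442 to SCO3453 (3804032 to 3814025) were lower in simulated 1g than on the ground, with a median of -1.65. Coordinates are those of the authors' tables and the RefSeq annotation of the same chromosome sequence (assembly ASM20383v1).

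The microgravity array shared 94 probes that were higher and 19 that were lower against both controls, and 13 probes went in opposite directions. Independent lists of these sizes would share 7.33 and 2.84. Across 8081 probes, which are not independent replicates, the 2 sets of differences correlated with r = 0.43. Both contain the same microgravity array, and 3 unchanged arrays with spot noise alone gave r = 0.50 in 100 simulations, with no 2-fold call. The covariance was 0.109 against 0.00344 in that simulation. The simulation holds no variation between arrays or cultures, so this gap does not measure an overlap beyond the shared array. How much of the overlap comes from the shared array was not separated.

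**Figure D3:**
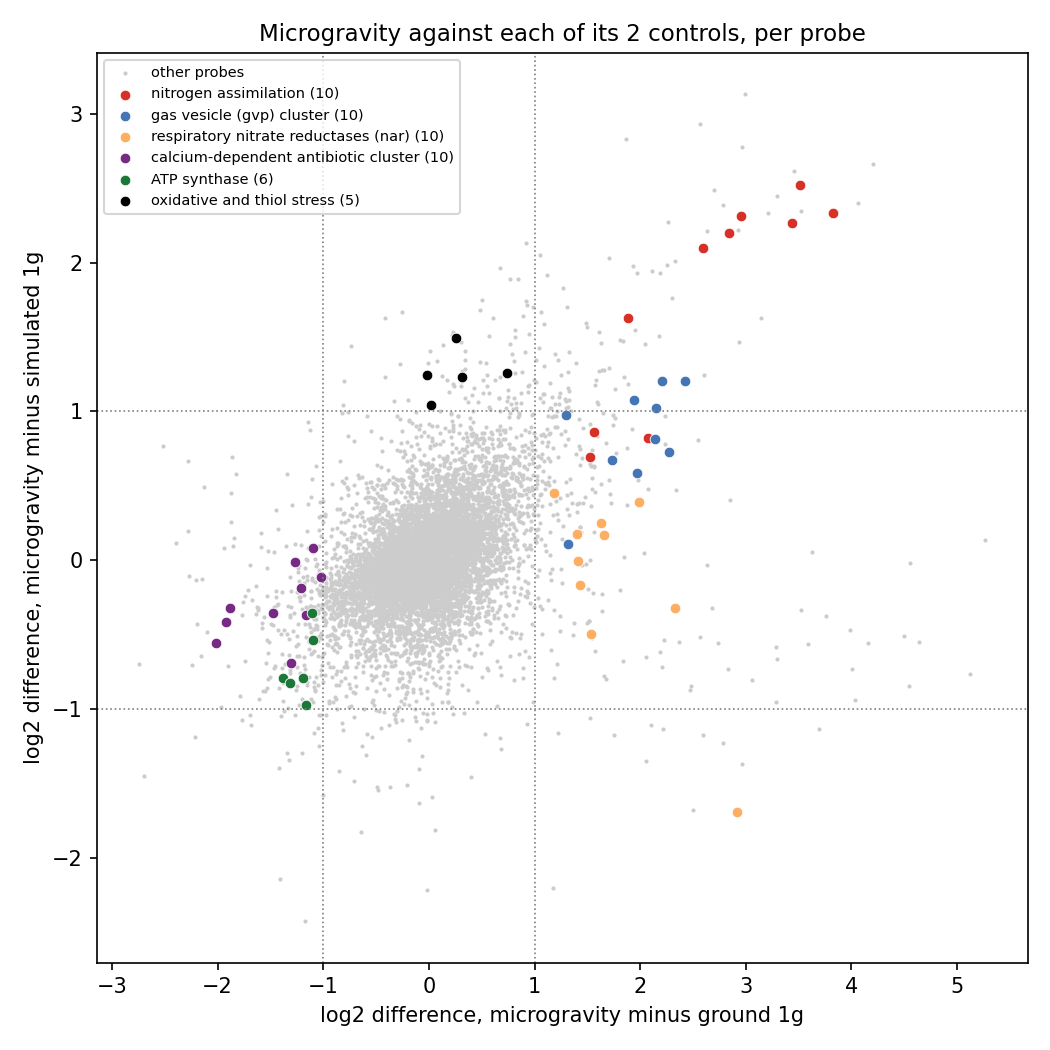
Each point is 1 of 8081 probes, with its log2 difference of microgravity minus ground on the x axis and of microgravity minus simulated 1g on the y axis; coloured points are named members of 6 gene lists and dotted lines mark 2-fold. Nitrogen genes reach 3.83 and 2.52 on the 2 axes, whereas thiol stress genes lie above 1 only on the y axis.

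The counts moved with the scaling. The spike-in probes put the median of all probes 0.35 (microgravity) and 0.38 (simulated 1g) above the ground array, so that spike-in scaling gave 772 higher and 86 lower probes for microgravity against ground, 90.0% higher in place of 54.1%, and 724 and 59 for simulated 1g, 92.5% in place of 53.4% (63.8% after cyclic loess). Scaling to the median of the probes gave 295 higher and 315 lower (48.4%) for microgravity and 223 and 224 (49.9%) for simulated 1g, and normexp 48.7% for the latter, so which direction holds more probes is not settled. All differences from the ground above are relative to the 75th percentile of each array, and the normexp alternative on median signals gave 40 lower probes in place of 84 in microgravity against simulated 1g.

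The authors' deposited tables held 271 probes for microgravity against simulated 1g, 178 higher and 93 lower, and 570 for microgravity against ground, 327 higher and 243 lower. Of these, 177 and 82, and 315 and 237, were past 2-fold in the same direction after 75th percentile scaling. The 2 deposited tables shared 124 probes, 111 of them in the same direction.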

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

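The normexp correction on median signals, the 75th percentile over spots and the median over spots were chosen after seeing the data; the other alternatives were fixed before. No paired analysis was possible because the groups share only 1 replicate number. The planned normexp on mean signals was not run because the files used here hold no mean signal, and the 2 planned summaries over several probes of a gene were not run because each named gene has 1 probe. None of the list medians and named-gene values past 2-fold changed sign under the alternatives run for them; the named genes were not rerun under other background filters, and the other called probes were not followed singly. Among alternative counts of 2-fold probes 52 stayed within 1.5 times and 14 did not. All 12 window counts stayed within it, but windows were rerun only with 7 loci and with quantile normalization, not under spike-in scaling or normexp. Of the correlation and overlap values 18 held. Of the list medians 333 moved by less than the standard deviation of the spike-in differences and 57 by more. Of the named-gene values 1537 moved by less than that and 383 by more, 161 of them under spike-in scaling and 143 under normexp. The 3-fold limit gave 51 higher and 10 lower probes for microgravity against simulated 1g, 131 and 47 for microgravity against ground, and 88 and 39 for simulated 1g against ground, by its own construction. Normexp on median signals, which changes the signal, the background correction and the offset together, gave 40 lower probes in the first comparison, 201 higher and 175 lower in the second and 129 higher in the third, with 58 and 7 probes shared in the 2 directions against both controls. Spike-in scaling, which adds 0.38 and 0.42 to every difference from the ground, gave 772 higher and 86 lower against ground for microgravity, 724 and 59 for simulated 1g, and 9 shared lower probes.

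That constant moved every list median against ground. For microgravity it gave 1.44 for actinorhodin, -0.91 for the calcium-dependent antibiotic, 2.09 for coelimycin, 1.56 for bld, -0.80 for ATP synthase, 1.70 for NADH dehydrogenase, -0.040 for heat shock, 0.64 for thiol stress, 1.95 for osmotic stress, 3.098 for nitrogen, 2.44 for gas vesicles, 1.96 for nitrate reductases and -0.78 for SCP1. For simulated 1g the same order ran 0.87, -0.73, 1.69, 1.49, -0.10, 1.46, 0.99, -0.60, 0.97, 1.19, 1.59, 1.97 and -0.59. Normexp gave, in microgravity against simulated 1g, 0.45 for actinorhodin, 0.33 for NADH dehydrogenase and 0.73 for gas vesicles; in microgravity against ground, 0.67 for actinorhodin, 1.17 for coelimycin, 0.75 for bld, 1.06 for NADH dehydrogenase, 1.32 for osmotic stress, 1.41 for gas vesicles and 1.40 for nitrate reductases; and in simulated 1g against ground, -0.91 for the calcium-dependent antibiotic, 0.85 for coelimycin, 0.74 for bld, 0.73 for NADH dehydrogenase, 0.11 for osmotic stress, 0.59 for nitrogen, 0.74 for gas vesicles, 1.42 for nitrate reductases and -0.90 for SCP1. Cyclic loess gave, for simulated 1g against ground, 0.54 for actinorhodin, -0.30 for ATP synthase, 0.72 for heat shock and -0.81 for thiol stress, and for microgravity against ground -0.14 for heat shock and 0.50 for thiol stress. Quantile normalization and the authors' value table both gave -0.41 for ATP synthase and -0.88 for thiol stress in simulated 1g against ground and -1.18 for heat shock in microgravity against simulated 1g. For the normexp, loess and quantile shifts the cause was not tested. By the scanner's flag, 33 probes on the ground array and 6 on each flight array were not well above background. This count says little about dim signals that passed the flag, so it does not show how many genes the background limited.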

Other observations

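The tests of explanations in this part were chosen after the results were seen. The nitrogen list and the planned settings were fixed before, but the median over its named members replaced the planned median of the whole list. The genes of the next paragraph, of the SCO0162 to SCO0220 stretch and of the sigR set were chosen after their values were seen. They are values of single arrays.

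The glycerol operon was higher in microgravity than in either control. Its regulator (SCO1658), uptake facilitator (SCO1659), glycerol kinase glpK (SCO1660) and glycerol-3-phosphate dehydrogenase (SCO1661), at 1776737 to 1781889 on the chromosome, had log2 differences of 2.33, 2.35, 2.45 and 2.39 from simulated 1g and of 3.21, 3.52, 3.29 and 2.78 from the ground. Elsewhere on the chromosome, a LacI-family regulator (SCO2745) and the carbohydrate transporter genes next to it (SCO2746 and SCO2747) had 2.48, 2.62 and 1.98 from simulated 1g. Of ribosomal protein genes outside the fixed list, 4 picked by their values were higher in microgravity than in simulated 1g: L36 (SCO0569) by 1.24, L33 (SCO0570) by 1.18, another L33 (SCO3428) by 1.30 and S14 (SCO3430) by 1.09. The 1 named member of the fixed list of 31, SCO4708, had -0.25 in that comparison, so no statement on ribosomal protein genes as a group follows, and against the ground only SCO3428, with 1.09, passed 2-fold. A cluster of membrane proteins around a cation-transporting ATPase, SCO0859 to SCO0863, stood out in simulated 1g: SCO0860 had -1.81 and SCO0861 -1.59 for microgravity minus simulated 1g, while the differences of microgravity from the ground were 0.06 and 0.03.

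The first pattern is the stretch from SCO0162 to SCO0220 with its 37 named genes. Their median difference from the ground was 2.78 in microgravity and 3.77 in simulated 1g, and it was -0.56 between the flight arrays. These genes have a name only by passing 2-fold between microgravity and a control, so the medians do not describe the unnamed loci of the stretch. The ground array, on which the pattern rests, also held 59.3% of the summed variance of the 3 arrays. That share counts every change common to both flight arrays, this stretch included, so it cannot tell a deviant ground array from an effect of flight. The scaling between arrays does not account for the pattern, since the spike-ins would raise every difference of microgravity from the ground by 0.38. The lowest median of that difference over 9 settings, which include a normexp background correction, was 2.52. Signals lost in the background were checked by the scanner's flag: 0% of these genes failed to be well above background on the ground array. Only 33 of 8116 ground probes failed that flag, so it says little about dim signals that passed it. The region holds the response regulator SCO0204 and a nitrate reductase, and less oxygen in the flight cultures may be a candidate explanation; of the 4 genes of the cytochrome bd oxidase locus, SCO3945 to SCO3948, 0 were in the authors' table as higher than ground, but only SCO3947 has a value, -0.19 for microgravity minus ground and 0.79 for simulated 1g minus ground, so this stays open. Flight and ground cultures also differed in launch and return, which cannot be told apart from growth in orbit.

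The second pattern is the nitrogen assimilation set, highest in microgravity. Scaling does not account for it: the spike-ins would change every difference of microgravity minus simulated 1g by -0.044, and the lowest median over 9 settings was 2.08. A difference between single cultures, for instance in how far each had used its nitrogen source, could produce it without gravity. The 2 cultures at 1g differed by a median of 0.77 in the same genes, and by 0.59 to 1.19 over 9 settings. That difference also holds flight against ground, so it does not measure the spread between like cultures. The genes of the set have a name only by passing 2-fold between microgravity and a control. Selection by itself therefore favours larger medians for microgravity than between the 2 cultures at 1g. With 1 culture per position, a difference between single cultures and an effect of gravity cannot be told apart.

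The third pattern is the lower level of sigR, rsrA, thioredoxin, methionine sulfoxide reductase and 2 ribosomal protein genes in simulated 1g than in microgravity. Whether the simulated 1g array or its culture stands apart in all genes is open: it held 15.4% of the summed variance of the 3 arrays, the smallest share (microgravity 25.3%, ground 59.3%), but these shares have no spread, and with 1 array per group this cannot be told apart from an effect on these genes. Scaling does not account for the difference between the flight arrays, since the spike-ins would change it by -0.044, but it moves the place of the ground array: the median ranged from -1.05 to -0.60 for simulated 1g minus ground and from 0.17 to 0.60 for microgravity minus ground. Between simulated 1g and ground 5 of the 9 genes were past 2-fold, and 0 under spike-in scaling, which adds 0.42 to each, so whether the set is low in simulated 1g only is open. No biological explanation was tested, and the design holds no further culture in simulated 1g.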
